A study of Homo sapiens with 10 samples.

How the data were processed

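Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in Nalm6, a human B-cell precursor leukemia line, in control cells (WT) and in cells with a CRISPR/Cas9 knockout of MondoA (KO). MondoA is the transcription factor encoded by MLXIP. Per the labels' protocols, cells were fixed with 1% formaldehyde for 9 min, 6% murine chromatin was added as a spike-in, and DNA was sheared to below 300 bp. Libraries were made with a size selection of 200 bp and 18 cycles of PCR. One antibody was against MYC and the other against MLXIP. The labels describe 10 libraries: MYC in WT and KO cells with 2 replicates each, MondoA in WT and KO cells with 1 each, and 4 inputs. Peak lists of the 6 immunoprecipitated libraries were analysed, and the inputs were not analysed here.

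Per the submitters' processing notes, bcl2fastq, Bowtie2 2.3.4, MACS2 2.1.1 and deepTools were used with the genome build hg19. The role of each tool, the control library given to the peak caller and any use of the spike-in are not given in the sources used here. The deposited lists are in the narrowPeak format of MACS2, with 1 list per library and no pooling of replicates. For each peak the authors deposited its position, a fold enrichment at the summit, a −log10 p-value, a −log10 q-value, the distance of the summit from the peak start and a score. That score equals 10 times the −log10 q, cut to a whole number. These values are the peak caller's own for each peak, and they were used only to describe, rank or filter peaks within a list. The lowest deposited −log10 q was 1.34 in the list labelled MYC KO replicate 1 and 1.35 in MondoA WT, below a q of 0.05. It was 2.00, 2.02, 2.04 and 2.10 in the other lists, below a q of 0.01. The lists therefore differ in their calling limit. Peak lists carry no read counts, so the depth of each library is unknown, and the number of peaks rises with depth and enrichment as well as with occupancy.

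Groups were taken from the labels. For both KO replicate 1 libraries the labels and the name of the deposited list give different antibodies. The list of the library labelled MYC KO replicate 1 names MondoA, and the list of the library labelled MondoA KO names MYC. The peak names written inside the 2 lists give the same antibodies as the names of the lists. Both are called "the library labelled" MYC KO or MondoA KO in the results. Because of this disagreement MYC comparisons between genotypes used KO replicate 2, and replicate 1 was added as labelled and with its 2 lists exchanged. This choice, which rests on the names of the lists, the main test of each comparison and the alternatives listed below were fixed before the data were examined. The comparisons at 514 and 12050 peaks per list, the distances between summits, the counts by decile of the MondoA peaks and among the 50 strongest, and the alternatives named as added were chosen after seeing the data.

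Peaks on chromosomes 1 to 22 and X were used; peaks on Y and 1 peak on the mitochondrial chromosome were set aside. No list held overlapping peaks. Lists were compared by overlap of at least 1 bp with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Shares are given with Wilson 95% intervals over peaks, which cover counting error only and not differences between cultures. The share that overlaps by chance was taken from 1000 random rotations of one list within each chromosome, up to the last peak end seen in any list. Rotated peaks fall on any DNA, not on open chromatin alone, so this is a low bar. WT consensus peaks of MYC are the peaks of WT replicate 2 that overlap a peak of WT replicate 1. The odds that a consensus peak was found in KO were compared between peaks with and without MondoA by a Mantel-Haenszel odds ratio over 10 strata (deciles) of fold enrichment (statsmodels 0.14.6). Numbers of MYC peaks were compared by an exact two-sided permutation test. On simulated data, overlap of 5000 peaks placed with a true share of 60% was found for 60% of them. A simulated odds ratio of 3 over 13378 peaks was recovered as 3.16.

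Alternatives were an overlap of at least 50% of the shorter peak, summits within 100 bp, a −log10 q of at least 5, a fold enrichment of at least 5, lists of equal length, other strata, and leaving out replicates. The regions named are the 5 of highest −log10 q of each kind: MondoA in WT, MYC in both WT replicates, those of the latter not found in KO replicate 2, and KO replicate 2 peaks in neither WT list. Coordinates are on hg19, 1-based. An hg19 genome or annotation was not used here, so peaks are given by position without gene names. The planned analyses of promoters, gene lists, E-box sequences and genomic location were not run, and the MLXIP locus was not checked for the knockout. The labels do not say whether replicates came from separate cultures.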

Results

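Binding of MYC and MondoA was mapped in Nalm6 B-cell precursor leukemia cells with and without MondoA. MYC with its partner MAX, and MondoA with its partner MLX, are basic helix-loop-helix leucine-zipper factors of one extended network, and MondoA is known to activate genes in response to glucose metabolites. MYC WT replicate 1 held 43215 peaks covering 16.8 Mb, with a median width of 264 bp and a median fold enrichment of 5.92. MYC WT replicate 2 held 13378 peaks covering 3.43 Mb, with a median width of 213 bp and a median fold of 4.89. MYC KO replicate 2 held 24351 peaks covering 5.78 Mb, with a median width of 186 bp and a median fold of 5.18. MondoA WT held 7883 peaks covering 1.46 Mb, with a median width of 160 bp and a median fold of 4.80. The library labelled MYC KO replicate 1 held 514 peaks covering 0.103 Mb, and the library labelled MondoA KO held 12050 peaks covering 2.44 Mb. Fold enrichments are the authors' values for each peak.

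**Figure D1:**
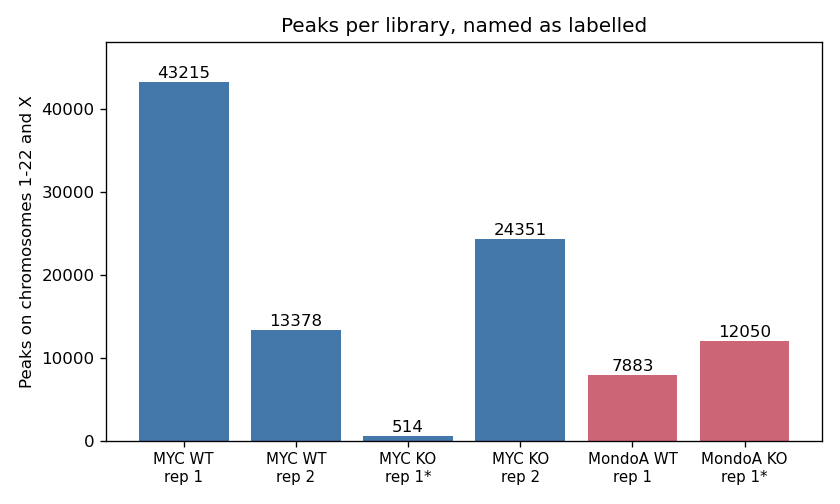
Number of peaks on chromosomes 1 to 22 and X in each of the 6 lists (bars; blue, MYC; red, MondoA; rep, replicate), named as labelled. Asterisks mark the 2 KO libraries whose peak names give the other antibody; counts run from 514 to 43215.

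The first comparison asked where MondoA bound in WT cells and whether these sites were lost in the knockout. The strongest MondoA WT peak lay at chromosome 8, 103665860 to 103666675, with a fold enrichment of 48.8. The next 2 were on chromosome 1, at 145455085 to 145455713 with a fold of 40.2 and at 145437491 to 145439389 with a fold of 37.4. The fourth was on chromosome 10, at 6205389 to 6206176, with a fold of 40.7. The fifth was on chromosome 19, at 18134665 to 18135077, with a fold of 28.8. None of these 5 regions had a peak in the 514-peak list labelled MYC KO replicate 1. In the list labelled MondoA KO a peak was present at 3 of them, the region starting at 145437491 on chromosome 1 and the regions on chromosomes 10 and 19.

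In the library labelled MondoA KO, 2772 of the 7883 MondoA WT peaks were found, a share of 35.2% (95% interval 34.1 to 36.2), against a mean of 0.167% for random placements. MYC lists cut to the same length of 12050 peaks (added) held 35.1% (WT replicate 2), 36.9% (KO replicate 2) and 42.9% (WT replicate 1). The 35.2% lay within the range of these MYC lists, so it does not show that MondoA stayed at its sites. When the lists of the 2 KO replicate 1 libraries were exchanged, so that the 514-peak list stood for MondoA KO, 390 were found, a share of 4.95% (4.49 to 5.45). The random placements then gave a mean of 0.0066%. The 514-peak list is too short to hold most of the 7883 peaks, so a low share was fixed by its length. Loss of sites in the knockout, or a low depth or enrichment, could each give a short list. Depth is unknown, so the 4.95% cannot tell these apart. Of the 514 peaks, 75.9% overlapped a MondoA WT peak. Among the 50 MondoA WT peaks of highest −log10 q, 27 had a peak in the library labelled MondoA KO and 17 in the library labelled MYC KO replicate 1. With 1 library per genotype this comparison has no replicate check.

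In a comparison added after seeing the data, the lists of both KO replicate 1 libraries were set against all others at equal length, with the 514 peaks of highest −log10 q from each. The list labelled MYC KO replicate 1 shared 143 of 514 peaks with MondoA WT, 19 with MYC WT replicate 2, 7 with MYC KO replicate 2 and 6 with MYC WT replicate 1. The list labelled MondoA KO shared 325 with MYC KO replicate 2, 286 with MYC WT replicate 1, 274 with MYC WT replicate 2 and 31 with MondoA WT. Over all its peaks, the list labelled MondoA KO overlapped MYC WT replicate 1 at 92.9% and MondoA WT at 23.1% of 12050 peaks. Over all its peaks, the list labelled MYC KO replicate 1 also overlapped MYC WT replicate 1, the longest list, more often than MondoA WT, at 85.2% and 75.9% of 514 peaks.

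**Figure D2:**
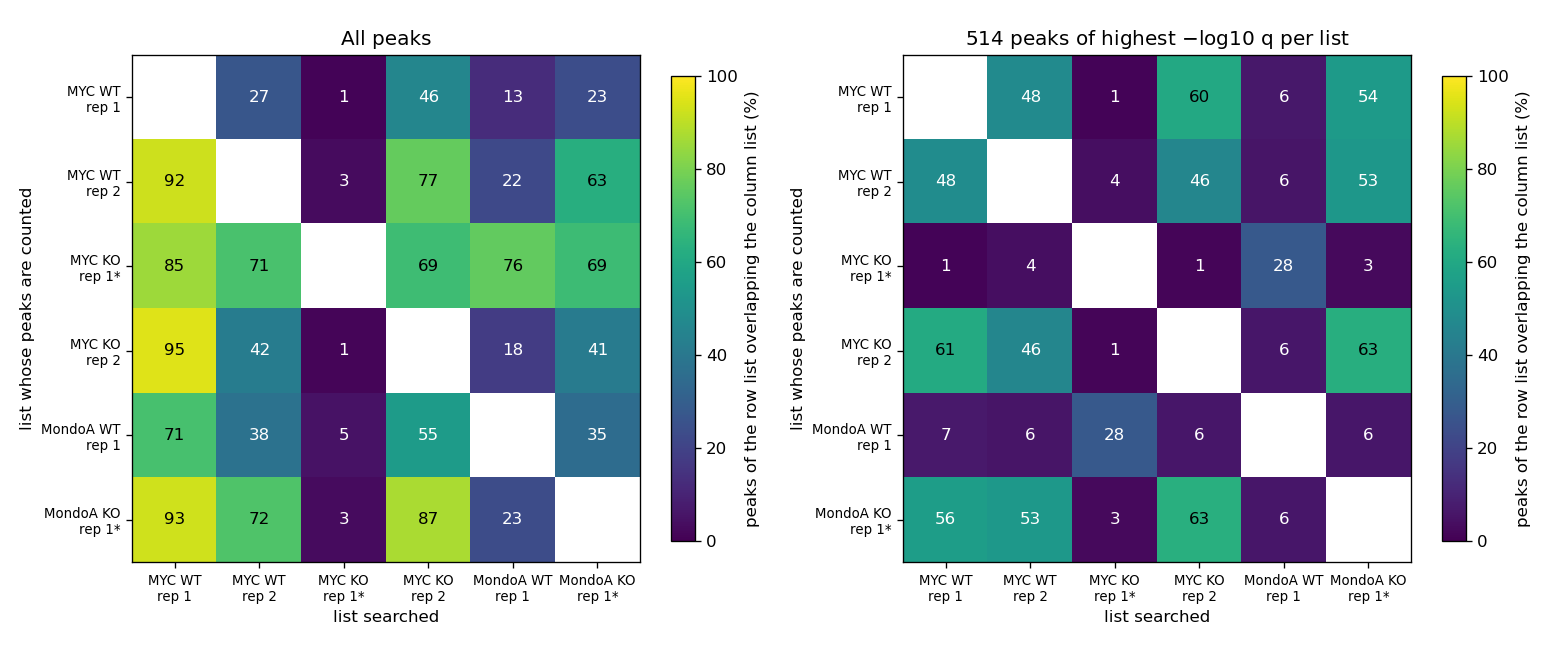
Percentage of the peaks of each row's list that overlap a peak of each column's list by at least 1 bp, for all peaks (left) and for the 514 peaks of highest −log10 q of each list (right). Asterisks mark the KO replicate 1 libraries, named as labelled; at equal length the list labelled MYC KO shared 27.8% of its peaks with MondoA WT and at most 3.70% with any list labelled MYC.

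The second comparison concerned MYC in WT cells. MYC sites recurred between WT replicates: 12334 of the 13378 peaks of replicate 2 had a peak in replicate 1, a share of 92.2% (91.7 to 92.6), against 0.996% for random placements. In the other direction, 26.8% of the 43215 peaks of replicate 1 were found in replicate 2. The strongest MYC region in both WT replicates lay at chromosome 1, 158985027 to 158985646, with a fold of 93.7 in replicate 2. A region on chromosome 2, at 146169605 to 146170519, had a fold of 67.8 and was present in all 6 lists. The other 3 of the 5 strongest lay on chromosome 1 at 62241666 to 62242250 (fold 58.6), on chromosome 2 at 203776025 to 203777039 (fold 39.2) and on chromosome 12 at 118794927 to 118795575 (fold 52.8). Each of the 5 also had a peak in MYC KO replicate 2. At equal length, with 13378 peaks in each list, the WT replicates shared 62.3% of peaks.

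The third comparison asked whether MYC binding changed when MondoA was absent. Most MYC sites common to both WT replicates were also found in the knockout: of the 12334 WT consensus peaks, 10090 were found in KO replicate 2, a share of 81.8% (81.1 to 82.5). The share was 66.6% when the list labelled MondoA KO was searched and 2.88% when the list labelled MYC KO replicate 1 was. With 514 peaks, the latter list could hold only a small part of the 12334. The 2.88% therefore cannot tell loss of sites from a low depth or enrichment, or from the other antibody that the list names. Of all 43215 peaks of WT replicate 1, without regard to WT replicate 2, 45.8% were found in KO replicate 2. The KO list holds 24351 peaks, so its length limits this share, which does not measure loss. In the other direction, 94.9% of the KO replicate 2 peaks were found in WT replicate 1. The 2244 consensus peaks that were not found had a lower −log10 q than those that were, with medians of 8.34 and 14.2, but a higher fold enrichment, with medians of 6.18 and 4.29. The strongest of the peaks not found was on chromosome 9, at 117080187 to 117080433, with a fold of 27.1 in WT replicate 2. The next 4 followed, on chromosome 13 at 113513483 to 113513753, on chromosome 20 at 23120224 to 23120457, on chromosome 6 at 160503720 to 160503927 and on chromosome 2 at 62570867 to 62571110. Their folds were 10.5, 14.1, 9.42 and 19.3.

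Of the 24351 peaks of MYC KO replicate 2, 23273 overlapped a peak of a WT replicate and 1078, or 4.43%, overlapped none. This small share rests on the long list of WT replicate 1: 5.07% of the KO peaks had no peak there and 57.8% had none in WT replicate 2. By comparison, 7.80% of the peaks of WT replicate 2 had no peak in WT replicate 1. The strongest of the 1078 was on chromosome 17, at 77186536 to 77186888, with a fold of 10.4. The next 4 lay on chromosome 2 at 217007318 to 217007582 (fold 15.8), on chromosome 4 at 40576029 to 40576186 (fold 14.8), on chromosome 2 at 12938009 to 12938192 (fold 14.5) and on chromosome 1 at 240748468 to 240748590 (fold 13.6). In the list labelled MondoA KO, 146 of the 1078 peaks were present, or 13.5%, including 4 of these 5. Of all 24351 peaks of KO replicate 2, 41.4% were present there, so the 1078 recurred less often than KO peaks in general. The list labelled MondoA KO held 486 of the 2244 WT consensus peaks that KO replicate 2 lacked, or 21.7%. It held 76.6% of the WT consensus peaks that were found in KO replicate 2.

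The difference in peak number between genotypes was not larger than that between replicates. Replicate 2 had 1.82 times as many MYC peaks in KO as in WT. Replicate 1 had 0.0119 times as many as labelled, and 0.279 times as many with the lists exchanged. The mean was 28297 ± 21098 peaks in WT (SD, n = 2) and 12433 ± 16855 in KO (SD, n = 2) as labelled. An exact two-sided permutation test gave p = 0.667, and 2 against 2 libraries cannot give a p below 0.333. WT and KO of replicate 2 shared 76.5% of the peaks of the shorter list, against 92.2% for the WT replicates, but at equal length they shared 60.2% against 62.3%. With the KO replicate 1 lists exchanged and 12050 peaks per list (also added), WT replicate 1 and KO replicate 2 shared most, at 76.3%. WT replicate 2 and the exchanged KO replicate 1 shared 67.6%, WT replicate 1 and the exchanged KO replicate 1 shared 63.3%, and the replicate 2 lists of WT and KO shared 59.39%. Within a genotype, the 2 KO lists shared 67.1% and the 2 WT lists 59.37%. Pairs of one genotype thus lay within the range of pairs of different genotypes or just below it. As labelled, this test of KO replicate 1 is limited to the 514 peaks described above.

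The fourth comparison asked how often MondoA and MYC occupied the same sites in WT cells. Of the 7883 MondoA WT peaks, 37.2% (36.2 to 38.3) overlapped a WT consensus MYC peak, and 18.7% did when the MYC and MondoA lists were cut to equal length. In MYC WT replicate 1, the longest list, 5591 or 70.9% (69.9 to 71.9) had a peak, and 42.9% when that list was cut to its 12050 peaks of highest −log10 q. In MYC WT replicate 2, 37.7% (36.6 to 38.8) had one. Random placements gave 0.197% for the consensus, 0.909% for replicate 1 and 0.209% for replicate 2. Of the WT consensus MYC peaks, 23.6% (22.8 to 24.3) had a MondoA peak. Within the peaks that overlapped, the median distance between summits was 38 bp for MYC WT replicate 1 and 33 bp for MYC WT replicate 2. Peaks that overlap have close summits by selection, so each MondoA peak was also moved at random among the places that overlap the same MYC peak. This gave medians of 149 to 162 bp and 107 to 121 bp over 1000 repeats, so summits lay closer together than overlap alone requires. The share with a MYC peak rose with the −log10 q of the MondoA peak, but not steadily with its fold enrichment. In the decile with the lowest −log10 q, 37.3% of MondoA peaks overlapped MYC WT replicate 1, and in the decile with the highest 96.7% did. By decile of fold enrichment the share was 95.8% in the lowest, 42.0% in decile 5 and 93.8% in the highest. All 50 MondoA peaks of highest −log10 q had a peak in MYC WT replicate 1, 30 in MYC WT replicate 2 and 41 in MYC KO replicate 2.

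**Figure D3:**
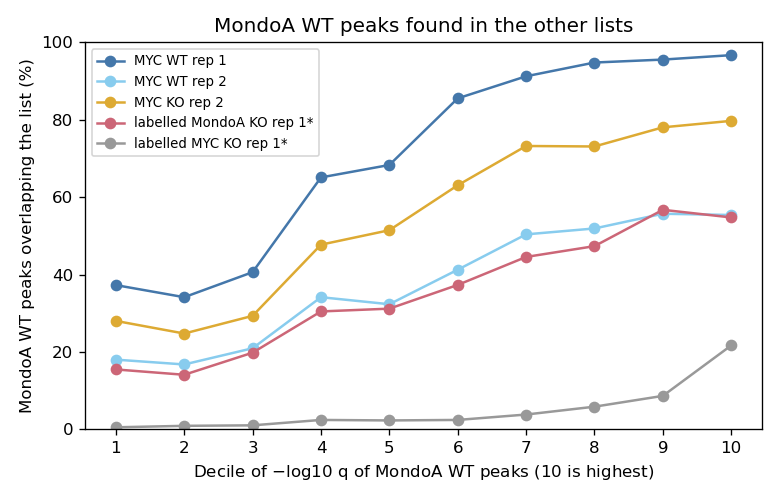
Percentage of MondoA WT peaks (y axis) that overlap a peak of each other list, by decile of their −log10 q (x axis; 788 or 789 peaks per decile). The share in MYC WT replicate 1 is 37.3% in the lowest decile and 96.7% in the highest, and that in the list labelled MYC KO replicate 1 (asterisk) 0.507% and 21.7%.

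The fifth comparison asked whether MYC sites that also held MondoA were lost more or less often in the knockout. They were found more often: 2651 of 2908 WT consensus MYC peaks with MondoA, 91.2% (90.1 to 92.1), had a peak in MYC KO replicate 2. Of 9426 peaks without MondoA, 7439 did, or 78.9% (78.1 to 79.7). The share was higher at sites with MondoA in each decile of MYC fold enrichment, and the Mantel-Haenszel odds ratio was 2.91 (2.53 to 3.35). It was 1.60 (1.32 to 1.92) among peaks with a fold of at least 5. With the KO replicate 1 lists exchanged, so that the list labelled MondoA KO was searched, it was 2.38 (2.15 to 2.64). It was 16.3 (12.3 to 21.5) when the 514-peak list labelled MYC KO replicate 1 was searched. That list is named for MondoA and is from KO cells. If it was made with the MondoA antibody, the 16.3 measures regions found again with that antibody and not MYC. Whether MondoA itself was bound there in KO cells was not tested. Within strata of −log10 q, with KO replicate 2 searched, the odds ratio was 2.25 (1.95 to 2.59). In a comparison added after seeing the data, MYC WT replicate 1, shortened to the 24351 peaks of highest −log10 q, took the place of MYC KO replicate 2. Over all WT replicate 2 peaks, the odds ratio was then 3.55 (3.08 to 4.08), against 3.54 (3.10 to 4.05) with KO replicate 2. Sites with MondoA recurred more often in another MYC list whether that list was from WT or KO cells. Intervals are over peaks, which are not replicates, and 1 KO library was used.

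**Figure D4:**
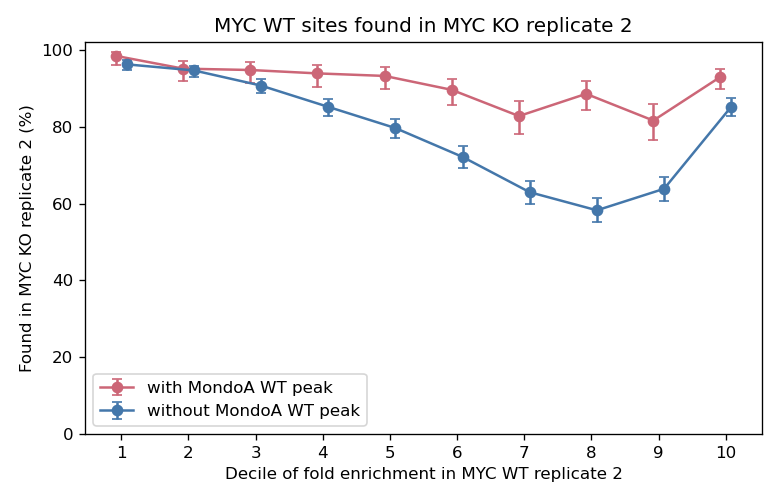
Percentage of WT consensus MYC peaks found in MYC KO replicate 2 (y axis), by decile of their fold enrichment in WT replicate 2 (x axis), for peaks with (red) and without (blue) a MondoA WT peak. Bars are 95% Wilson intervals over peaks. The gap was widest in the eighth decile, where 88.6% of peaks with MondoA and 58.3% without it were found. It was narrowest in the second decile, at 95.2% and 94.7%.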

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

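The tests in this part were chosen after the values were seen. Peaks on chromosome Y, which entered no comparison, were present in KO lists and nearly absent from WT lists. The 3 KO lists held 48 peaks on Y and the 3 WT lists held 3. As a share of all peaks this was 0.194% in the library labelled MYC KO replicate 1, which rests on 1 peak of 515 (95% interval 0.0343 to 1.09), 0.157% in the library labelled MondoA KO and 0.115% in MYC KO replicate 2. It was 0.00231% in MYC WT replicate 1 and 0.0149% in MYC WT replicate 2. MondoA WT had 0 of 7884, which allows a share of up to 0.0381% by the limit of 3 counts and 0.0487% by the Wilson interval used for the other lists. The intervals of the 2 long KO lists, 0.101 to 0.246 and 0.0795 to 0.166, lay above those of the MYC WT lists, 0.000408 to 0.0131 and 0.0041 to 0.0545, while that of the 515-peak list lay above that of MYC WT replicate 1 and overlapped those of MYC WT replicate 2 and MondoA WT. An exchange of the KO replicate 1 lists leaves the genotypes as they are. Lists of both antibodies may come from the same cells of a replicate, so each genotype has at most 2 independent samples here, and 2 against 2 cannot give a two-sided permutation p below 0.333. The ratio of the mean share in KO to that in WT was 27.0 on Y and between 0.822 and 1.21 on every other chromosome. The value on Y rests on the 3 WT peaks: it was 134 without MYC WT replicate 2, and 18.0 to 30.6 when each of the other lists was left out. The lists labelled MondoA KO and MYC KO replicate 2 had 15 peaks of KO replicate 2 on Y in common. Of these, 1 was also in both MYC WT lists, at 21154570 to 21154969. The other 14 lay between 2709571 and 22944606, and the strongest was at 6777260 to 6777507, with a fold of 28.6.

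List length does not account for this: at the share of the KO lists, MYC WT replicate 1, the longest list, would hold 56.1 peaks on Y and held 1. Reads from copies on other chromosomes that were placed on Y would be present in WT cells too, but 14 of the 15 shared peaks were in no WT list; this value is part of the pattern and not a separate test of it. Peaks on Y recurred between the 2 long KO lists about as often as elsewhere: 84.2% (62.4 to 94.5) of the 19 in the list labelled MondoA KO were in MYC KO replicate 2, against 87.3% on chromosomes 1 to 22 and X. Fewer copies of Y in the WT cells than in the KO cells is a candidate explanation that these values leave open. It cannot be told apart from a different control library or region filter in the peak calling of WT and KO, since neither is described in the sources used here. The tag blf, which the sources do not explain, was part of the peak names in the 2 lists named for MondoA. No list named for MYC carried it, in WT or KO, so this tag followed the antibody and not the genotype.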

How the results depend on the processing

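Values are given in the order of the main value and then the alternatives; the alternatives named as added were chosen after seeing the data. The share of MYC peaks shared by the WT replicates, 92.2%, was 91.7% with an overlap of at least 50% of the shorter peak, 80.6% with summits within 100 bp, 69.8% with a fold of at least 5 and 62.3% at equal list lengths. The share of WT and KO in replicate 2, 76.5%, was 75.8%, 69.9%, 50.7% and 60.2% under these settings. In replicate 1 it was 85.2% as labelled and 92.9% with the lists exchanged. The shorter list was WT in replicate 2 but KO in replicate 1. The replicate 1 values therefore count KO peaks found in the 43215 WT peaks and are not like the 76.5%. The share of WT consensus peaks found in KO, 81.8%, was 78.3% with summits within 100 bp, 64.4% with a fold of at least 5 and 85.6% at equal lengths. It was 2.88% with KO replicate 1 as labelled and 66.6% with the lists exchanged, and leaving out a WT replicate gave 45.8% to 76.5%. The share of MondoA WT peaks found in the library labelled MondoA KO, 35.2%, was 33.1%, 30.1%, 18.8% and 26.1% under the first 4 settings, 42.2% with a −log10 q of at least 5, and 4.95% with the lists exchanged. The share of MondoA WT peaks that overlapped MYC, 37.2%, was 35.3%, 28.5%, 18.6% and 18.7% under the same 4 settings and 45.3% with a −log10 q of at least 5; leaving out a WT replicate gave 37.7% to 70.9%. Lists shorten under the fold and equal-length settings, and the length of the 514-peak list caps the 2.88% and the 4.95%. The length of KO replicate 2, with 24351 peaks, limits the 45.8% of the longer WT replicate 1. The cause of each change was not tested. The odds ratio for MYC sites with MondoA, 2.91, had an interval above 1 under each alternative run, from 1.60 with a fold of at least 5 to 3.55, except that KO replicate 1 as labelled, with 514 peaks, gave 16.3. The ratio of mean MYC peak numbers, KO to WT, was 0.439, and 0.643 with the lists exchanged. It turned to 1.82 without replicate 1 and was 0.0119 without replicate 2, and 0.861 without the KO replicate 1 library (added). With a replicate block, the ratio within replicate numbers was 0.147; 2 pairs cannot give a sign-flip p below 0.5. With the lists exchanged, same-numbered MYC lists deviated in opposite directions (correlation −0.12 over 45779 regions, −0.30 over 19755 at equal lengths, and 0.31 as labelled). The crossed pairing of WT replicate 1 with KO replicate 2 (added) shared 94.9% of 24351 peaks. At 12050 peaks per list with the lists exchanged (added), the WT replicates shared 59.37%, WT and KO 59.39% in replicate 2 and 63.3% in replicate 1, and the crossed pairing 76.3%. MYC WT replicate 1 alone at that length (added) overlapped 42.9% of MondoA WT peaks. With the lists exchanged (added), the blocked ratio of peak numbers was 0.712. This ratio of geometric means is the same however replicates are paired, so it differs from 0.147 through the exchange alone. The analyses of gene lists, E-box sequences and genomic location were not run. Depth is unknown for every list, so a peak missing from a shorter list may be below its calling limit, which the fall from 92.2% to 62.3% at equal lengths also bears on.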

Other observations

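Not every MondoA peak had a MYC peak called at its site. Of the 7883 MondoA WT peaks, 2256 overlapped no peak of either MYC WT list. They had about the same median fold as the 5627 others, 4.86 against 4.79, but a lower median −log10 q, 3.63 against 7.72, and were narrower, with medians of 127 and 178 bp. MondoA WT was called to a q of 0.05 and the MYC WT lists to 0.01. Whether these unequal limits account for the 2256 was not tested. Among the 100 MondoA WT peaks of highest −log10 q, 33.0% had another peak within 10 kb (interval 24.6 to 42.7), against 25.9% (24.9 to 26.9) of all others, so the intervals overlap. MYC WT replicate 2 gave 51.0% and 44.7%.

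A set of 229 regions, 44.6% of the 514 peaks labelled MYC KO replicate 1, had a peak in all 6 lists. In MondoA WT these stood at a median percentile of 86.0 by −log10 q. The region on chromosome 2 at 146169605 to 146170519 was one of them.

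The 2 tests of the next pattern were chosen after overlaps of the lists had been seen. Both KO replicate 1 lists resembled the lists of the other antibody. At 514 peaks per list, the list labelled MYC KO replicate 1 shared 143 with MondoA WT and at most 19 with any other list, and the list labelled MondoA KO shared 31 with MondoA WT and 274 or more with the MYC lists of the other 3 libraries. An exchange of labels between these 2 libraries may account for both; the antibody in the peak names and the lower calling limit of the 514-peak list, which only MondoA WT shares, point the same way, though over all its peaks the 514-peak list overlapped the long MYC WT replicate 1 list more often than MondoA WT, at 85.2% against 75.9%. A low yield of the MYC immunoprecipitation would leave the strongest MYC sites, but 7 of the 514 strongest MYC KO replicate 2 regions were shared, although 68.9% of the 514 peaks had a peak somewhere in the 24351 of that list. If the labels are right, the same 7 argue against a change of MYC binding common to both KO replicates as the source of this pattern. With the lists exchanged, the 7 say nothing about MYC binding in KO cells. The list labelled MondoA KO then stands for MYC, and it shared 325 of 514 peaks with MYC KO replicate 2. A MondoA antibody that binds MYC sites once MondoA is gone was not tested.

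The 2 tests of the last pattern were also chosen after its values were seen. MYC sites with MondoA were found in MYC KO replicate 2 more often than other MYC sites. Within strata of −log10 q crossed with width, as measured in WT replicate 2, the odds ratio was 2.17, with a lower limit of 1.88. The strata are coarse and come from WT replicate 2 alone, so they cannot exclude that stronger or wider MYC sites are the cause. The pattern was also present without the knockout: the odds ratio was 3.55 when MYC WT replicate 1 at equal length was searched in place of MYC KO replicate 2, where it was 3.54. MYC WT replicate 1 and MondoA WT carry the same replicate number and may come from the same cells. The near equality therefore cannot exclude that the knockout plays a part. A hypothesis is that MondoA peaks mark accessible sites where any MYC list is likely to have a peak, which would need an independent measure of accessibility to test.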
